A study of Mus musculus with 6 samples.

How the data were processed

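RNA was measured in 6 libraries of B cells taken from mouse lung with B220 microbeads, 3 from control mice and 3 from mice with severe allergic airway inflammation. Per the labels' protocols, the severe asthma mice received 10 μg of lipopolysaccharide (LPS) and 25 μg of house dust mite extract (HDM) in 35 μl of buffer into the trachea on each of days 0 to 2, then HDM alone on each of the 8 days from day 7 to day 14. Control mice received buffer alone. Polyadenylated RNA was enriched with oligo(dT) beads, fragmented and made into libraries with a NEBNext Ultra kit, per the labels' protocols, and none of the sources used here states whether strand was kept or used in counting. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the mouse genome build mm10, with no role or order.

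The authors deposited a table of 84748 mRNA transcripts, a table of 34504 non-coding transcripts and a table of the 2977 genes that they called changed. Each of the deposited tables holds a library-size-adjusted signal per library, and each such value could be rebuilt, within 0.001, from a whole number of reads by the quantile adjustment of edgeR, which brings each group to 1 common library size with 1 dispersion per table (0.0474 for mRNA, 0.0305 for non-coding RNA and 0.0501 for the called genes). Inverting the adjustment gave whole reads, within 0.05, for 100% of the 499202 mRNA values above 0, of the 99626 non-coding values and of the 17695 values in the called table. No header names the tool that made this adjustment. The log2 fold changes and the p-value and q-value columns in the deposited tables are the authors' own, per the file headers, as are the q-values of the deposited term tables, and no source used here names the authors' test. The called table holds only genes with an absolute log2 fold change of at least 1 and a q-value under 0.05.

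The design assumed whole counts. Since the deposited values are adjusted, the test that had been fixed for normalized values was used: limma-trend with robust empirical Bayes on log2(value + 1), two-sided, over genes with a mean value of at least 1, with Benjamini-Hochberg adjustment over each table and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Each gene was represented by its transcript of the highest mean value, because reads count for every isoform they overlap. The reads of that transcript had a median ratio of 0.999 to the gene's own reads across the called genes, and the log2 fold changes of the called genes correlated between both tables with a Spearman rho of 0.998 across genes, which are not independent replicates. This left 21774 mRNA genes. Of the non-coding table, 7933 non-coding transcripts of coding genes were set aside and 16887 non-coding genes kept.

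Depth was 16498219 to 18054903 reads per library over the mRNA genes. Simulated data of the mRNA comparison, drawn from the real means with 200 genes changed, showed what this depth and spread allow when few genes change: of 15746 genes tested with limma, 11.9% of 67 genes changed 1.5-fold, 56.7% of 67 genes changed 2-fold and 80.3% of 66 genes changed 4-fold passed the threshold, and 9 unchanged genes did. The adjusted threshold loosens as more genes change, so these shares do not carry over to the real comparison, which called 5525 genes. A simulated list of 20 genes changed 2-fold passed camera, with the preset and with an estimated correlation, and 0 of the unchanged lists passed with the preset one. The simulated genes varied independently of each other, so this does not test camera on lists whose genes vary together. The read recovery, tested on 6000 simulated transcripts, returned 100% of the values.

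Gene lists (32 lists of B cell states, lymphoid tissue, inflammation, metalloproteinases, other cell types, RNA quality and sex-linked genes) were written before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. Of these lists, 29 had at least 3 measured members and were tested as 1 family with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Of the 12 genes of the immunoglobulin constant region and the 13 mitochondrial transcripts 0 were matched by symbol, and of the sex-linked list only Xist was. Camera compares a list with all other genes. Its calls were repeated with a correlation estimated for each list, and with fry, which tests whether a list's own genes change and compares them with no other gene.

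Named genes were Mmp12, the 10 risen and 10 fallen mRNA genes and the 5 risen and 5 fallen non-coding genes with the largest log2 change among those past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, up to 4 members of each list with the smallest p (up to 2 of the highest mean where none passed), and up to 3 members of the highest mean in each list of another cell type. The rule gave 147 genes, 132 of them past the threshold, and not all of them are reported here.

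The labels number the libraries of each group 1 to 3 without saying what the numbers mean. Deviations from the group means correlated at 0.41, 0.13 and 0.14 between same-numbered libraries, all above the minimum of 0.1 set for pairing. The numbers were therefore treated as possible pairs in an alternative fit, while the main fit used the group alone. The source of this pairing is the data alone, and control 2 correlated more with severe asthma 3 (0.18), and control 3 with severe asthma 2 (0.2), than with their own numbers. A fit with the replicate number as a block is given beside a result where it changes a call. Libraries of 1 group differed beyond sampling noise, with chi-square values per gene of 8.65 to 57.9, the highest for control 1 against control 2, so none was counted as a repeat.

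Alternatives were the replicate block, DESeq2, limma-voom, edgeR with RLE factors, scaling by total reads alone, no filter, a stricter filter, a minimum of 2-fold, glmTreat against 1.5-fold, both tables in 1 fit, pseudocounts of 0.1 and 5, and each library left out in turn. Alternatives added after the data had been seen were the edgeR quasi-likelihood test on the recovered reads with TMM factors, which called 4970 of 13418 mRNA genes (4538 shared with the limma calls, all in the same direction) and 285 non-coding genes, curated transcripts only, a mean value of at least 10, both libraries numbered 1 left out, and 8 further gene lists. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.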

Results

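B cells were selected from dissociated lung tissue with B220 microbeads and profiled by RNA sequencing in 3 control libraries and 3 libraries from mice with severe asthma, induced by LPS and house dust mite. The comparison asks which genes of lung B cells differ in severe asthma, in a study of inducible bronchus-associated lymphoid tissue, the lymphoid aggregates that form in inflamed airways. The mRNA genes took 16498219, 16634865 and 17580562 reads in control libraries 1 to 3 and 17123386, 17299344 and 18054903 in severe asthma libraries 1 to 3. Reads were found for 15614 to 16193 mRNA genes per library, and the 10 most abundant genes held 4.19% to 5.27% of the reads. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Values are the deposited library-size-adjusted read counts, given as mean ± SD, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

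Mmp12, the macrophage elastase named in the study's title (mm10, chromosome 9, 7344397 to 7360461, plus strand), rose from 43.7 ± 30.03 (SD, n = 3) in control to 3802 ± 2395 (SD, n = 3) in severe asthma. Its log2 fold change was 6.29 (SE 0.815, adjusted p = 0.00551), the 7th largest rise among the mRNA genes tested. The authors' deposited table gives Mmp12 a log2 fold change of 6.39 and a q-value of 2.69e-22. Control libraries 1 to 3 held 32.4, 21.0 and 77.8, and severe asthma libraries 1 to 3 held 1037, 5196 and 5173. Severe asthma 1, which had the lowest Mmp12 value of its group, also had the group's lowest values of Chil3 (15830, against 72560 and 44300) and Lyz2 (49850, against 92260 and 61800), both abundant in macrophages, but not of Apoe (33660, against 40240 and 28540), another macrophage gene. A two-sided exact permutation test of the 6 Mmp12 values gave p = 0.1, the smallest that 3 against 3 samples allow. With limma-voom the call was lost (log2 fold change 6.22, adjusted p = 0.0753), and over 19 alternatives the adjusted p ran from 2.07e-12 to 0.0753.

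Across the mRNA table, 3262 genes rose and 2263 fell in severe asthma, of 15759 tested. Of these, 792 rose and 1677 fell at least 2-fold. The groups did not overlap for 8397 genes (53.3%), where chance gives 10%. The largest rises included Saa3, an acute-phase serum amyloid gene (3.87 ± 3.59 to 1213 ± 331, SD, n = 3, log2 fold change 8.19), Inhba, the activin A subunit (12.7 ± 8.39 to 1936 ± 335, log2 fold change 7.29), H2-M2, a non-classical class I gene (log2 fold change 6.81), Gatm, an enzyme of creatine synthesis (5.29), and AA467197 (4.98), with adjusted p of 0.000223 to 0.000719. Gpnmb (log2 fold change 5.09) and Trem2 (4.94), lysosomal and lipid-sensing genes of macrophages, rose as well. The call of Gpnmb was lost without control 1 (adjusted p = 0.0662), and that of Trem2 without control 1 (0.111), severe asthma 2 (0.0773) or severe asthma 3 (0.0748) and with the replicate block (0.06). The largest falls included Bpifa1, a secreted protein of airway epithelium (3946 ± 1338 to 164 ± 22.1, log2 fold change -4.54, adjusted p = 0.000357), and Adcy8 (log2 fold change -4.84, adjusted p = 0.00408). The other 8 fallen genes were Lrat, Col13a1, Inmt, Pdgfra, Svep1, Slc16a9, Egflam and Pcolce2, with log2 fold changes of -5.16 to -4.55. Of these, Lrat, Col13a1, Inmt, Slc16a9, Egflam and Pcolce2 lost their call without severe asthma 3 (adjusted p 0.0502 to 0.0822), Lrat, Pdgfra and Egflam without severe asthma 2 (0.0501 to 0.0665), and Inmt and Egflam without control 1 (0.0539 and 0.0778), while limma-voom lost all 8 and Adcy8 (0.0707 to 0.13). All 8 were highest in control 1, as with Inmt (5554, against 1487 and 1099 in controls 2 and 3). Inmt and Pdgfra belong to the list of fibroblast and smooth muscle genes, so these falls need not lie in B cells. As macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages), the largest rises need not all lie in B cells either.

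The split of the mRNA calls depended on the scaling, as 1920 rose and 3111 fell with scaling by total reads alone. On recovered reads, with other tests over other sets of tested genes, 2436 rose and 2858 fell with DESeq2, 2557 and 2413 with edgeR and TMM factors, and 2393 and 2588 with edgeR and RLE factors. With limma-voom on recovered reads, 2396 rose and 1352 fell. The median log2 fold change of all genes was 0.06, against -0.08 with total reads alone. Counts fell to 1575 risen and 728 fallen without severe asthma 2, to 1627 and 782 without severe asthma 3, and to 1312 and 387 with no filter on low values, under which 48 of the 147 named genes lost their call.

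Germinal centre genes rose together. Of 15 tested, 11 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 2.08 (camera adjusted p = 2.13e-06, but adjusted p = 0.417 with an estimated correlation). Mybl1, the transcription factor A-Myb, rose from 37.3 ± 4.56 to 1026 ± 206 (SD, n = 3, log2 fold change 4.73, SE 0.178, adjusted p = 7.99e-05). Gcsam, a signalling adaptor of germinal centre B cells, rose from 5.41 ± 4.22 to 476 ± 65.8 (log2 fold change 6.40), Nuggc from 30.6 ± 4.86 to 628 ± 103 (4.31) and Mef2b, a transcription factor upstream of Bcl6, from 35.2 ± 11.8 to 690.4 ± 72.0 (4.30). All 25 cell cycle genes rose, with a median log2 fold change of 2.70 (camera adjusted p = 3.05e-17, adjusted p = 0.417 with an estimated correlation), and all 25 passed adjusted over the list alone. Among them were the mitotic regulators Plk1 (41.6 ± 9.73 to 436 ± 68.6, log2 fold change 3.37) and Cdc20 (2.70) and the replication licensing genes Mcm3 (1.30) and Mcm6 (1.098). Cell cycle genes are not particular to B cells, and macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages).

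**Figure D1:**
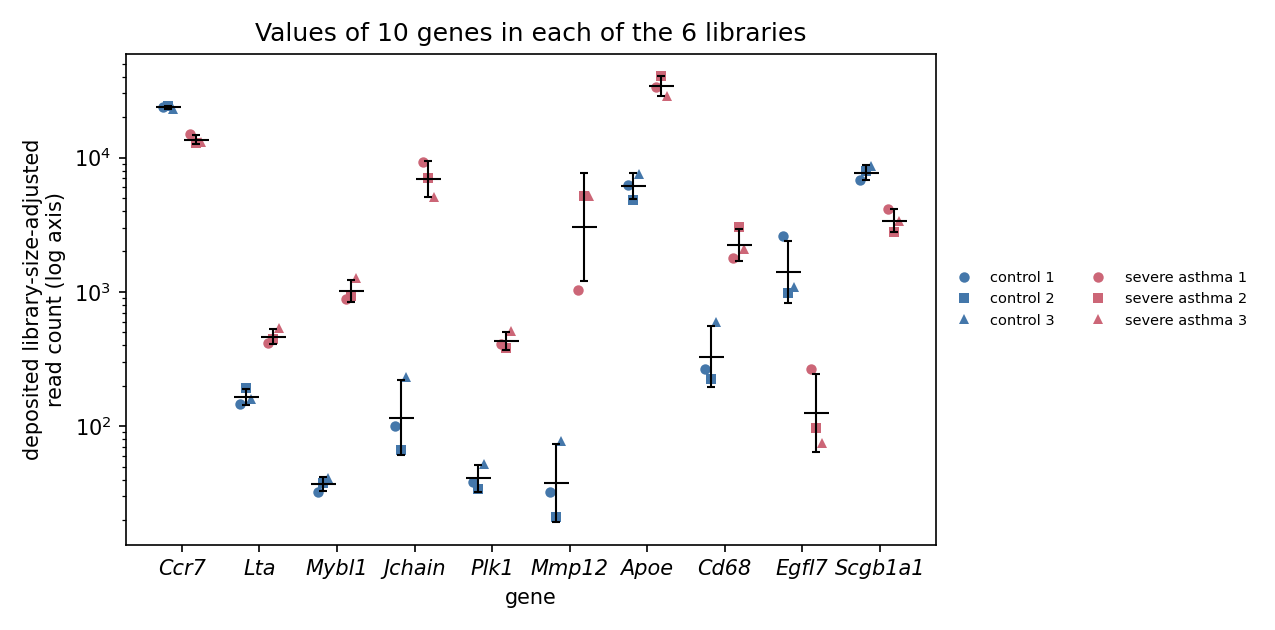
Library-size-adjusted read count (log axis) of 10 genes in each library, with control in blue, severe asthma in red and a marker shape per replicate number. Horizontal lines mark the mean and bars the SD of the log10 values (n = 3 per group); Mmp12 lies between 21.0 and 77.8 in control and between 1037 and 5196 in severe asthma, and Ccr7, Egfl7 and Scgb1a1 are lower in severe asthma.

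Plasma cell genes rose on balance: 9 of 18 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.53 (camera adjusted p = 0.000563, adjusted p = 0.417 with an estimated correlation). Jchain, which joins IgM and IgA into polymers, rose from 134 ± 89.0 to 7140 ± 2132 (SD, n = 3, log2 fold change 5.89, adjusted p = 0.00189), a call lost when both libraries numbered 1 were left out (adjusted p = 0.052). Mzb1, a chaperone of immunoglobulin secretion (log2 fold change 1.12), Slamf7 (1.11) and Xbp1, the transcription factor of the secretory programme (0.60), also rose. Of 18 genes of endoplasmic reticulum stress and secretion, 10 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 0.00878, adjusted p = 0.507 with an estimated correlation), among them Sdf2l1 (1.41), the translocon subunit Sec61b (0.83) and Ssr4 (0.62). Of 15 genes of B-1 and memory B cells, 7 of which other lists also hold, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.012, adjusted p = 0.417 with an estimated correlation). These included Cd300lf (2.41), Zbtb32 (2.11) and Bhlhe41, a transcription factor of B-1 cells (1.20). As macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages), the rise of Cd300lf cannot be assigned to B cells alone.

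All 14 glycolysis genes rose, also adjusted over the list alone, with a median log2 fold change of 0.75 (camera adjusted p = 1.04e-08, adjusted p = 0.417 with an estimated correlation). Hk2, the inducible hexokinase, rose from 152 ± 10.5 to 475 ± 72.5 (SD, n = 3, log2 fold change 1.63), and Tpi1 (1.17), Gapdh (1.05) and Pgam1 (1.06) about doubled. Gapdh and Pgam1 have processed pseudogenes whose reads the counting could share, so their values are uncertain. Genes of antigen presentation by MHC class II rose in 6 of 12 cases and fell in 0 (7 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.00893, adjusted p = 0.59 with an estimated correlation). Ctss, the protease that trims the invariant chain, had the largest log2 fold change of this list (1.76), followed in the named genes by Ciita, the master regulator of class II genes (8828 ± 377 to 13800 ± 45.1, 0.65), H2-Oa (0.52) and H2-DMa (0.45). Ctss is abundant in macrophages too, and glycolysis genes are not particular to B cells. Macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages).

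General B cell markers moved little. Of 20 identity genes, 3 rose and 1 fell (0 and 1 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 0.492). Cd55, a complement regulator, fell from 12280 ± 472 to 9297 ± 307 (SD, n = 3, log2 fold change -0.40, adjusted p = 0.00576). Cd72 (log2 fold change 0.78), Cd79a (0.41) and Cd22 (0.31) rose with adjusted p of 0.042 to 0.0468. Each of these 3 calls was lost without control 3 or without any 1 severe asthma library (adjusted p 0.0715 to 0.153), that of Cd22 also without control 1 (0.0528), and all 3 with total reads alone (0.0755 to 0.22). Of 20 activation genes, 8 of which other lists also hold, 6 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.367), with the smallest p-values for Egr2 (log2 fold change 1.81) and Cd44 (0.68). The median of the activation list was 0.042 without control 3 and turned to -0.06 without severe asthma 1.

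Genes of lymphoid tissue formation went both ways. Of 16 tested, 4 rose and 4 fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.04 and a mean of 0.05 (camera direction down, adjusted p = 0.577). Without severe asthma 1 the median was -0.471, and without severe asthma 3 it turned to 0.12. Lta, encoding lymphotoxin alpha, rose from 165 ± 23.1 to 467 ± 60.5 (SD, n = 3, log2 fold change 1.49, adjusted p = 0.000743). Ltb, its membrane partner, rose from 4463 ± 744 to 7119 ± 858 (0.68), a call lost with no filter on low values (adjusted p = 0.0673). Ccr7, the receptor that guides cells into T cell zones, fell from 23590 ± 743 to 13610 ± 1135 (log2 fold change -0.80, adjusted p = 0.000936), and Cxcr5, the receptor for follicles, from 8416 ± 472 to 5817 ± 408 (-0.53, adjusted p = 0.00368). Of 15 homing and adhesion genes, 4 rose and 4 fell in either adjustment, with a median of 0.03, a mean of 0.12 and a camera direction of down (adjusted p = 0.739). Ccr6, the receptor for Ccl20, rose from 1010 ± 24.4 to 2511 ± 96.8 (1.31), and Itgal, the integrin LFA-1 alpha chain, rose as well (0.59).

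Matrix metalloproteinases and their inhibitors, a list that includes Mmp12, went both ways. Of 20 tested, 6 rose and 6 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.01, a mean of 0.18 and a camera direction of down (adjusted p = 0.675). Mmp19 rose from 232 ± 97.1 to 1794 ± 653 (SD, n = 3, log2 fold change 2.95, adjusted p = 0.00614), a call lost without both libraries numbered 1 (0.0502). Mmp3, stromelysin-1, fell from 53.0 ± 16.8 to 4.18 ± 2.82 (-3.53, adjusted p = 0.00463), and Mmp28, epilysin, fell as well (-3.15, adjusted p = 0.00472, but 0.0666 with limma-voom). In the same libraries genes of monocytes and interstitial macrophages were higher (median 2.57) and endothelial genes lower (median -3.31). The changes of Mmp19, Mmp3 and Mmp28 therefore cannot be assigned to B cells alone.

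Macrophage genes were higher in the severe asthma libraries. Of 14 genes of monocytes and interstitial macrophages, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 2.57 (camera adjusted p = 1.96e-05, adjusted p = 0.445 with an estimated correlation). Apoe rose from 6227 ± 1362 to 34150 ± 5865 (SD, n = 3, log2 fold change 2.46, adjusted p = 0.00058), and Cd68 from 363 ± 205 to 2299 ± 658 (2.76), the latter losing its call without both libraries numbered 1 (adjusted p = 0.112). Lyz2, the most abundant of them, rose from 11870 ± 5425 to 67970 ± 21870 (2.60, adjusted p = 0.0125, but 0.0705 with the replicate block). Of 14 alveolar macrophage genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.11, camera adjusted p = 0.0232, adjusted p = 0.771 with an estimated correlation), and the call on the alveolar macrophage list was lost without control 1 (0.0664) or control 2 (0.132). Itgax (log2 fold change 2.82), Atp6v0d2 (3.22) and Chil3 (3.87) had its smallest p-values. The call of Atp6v0d2 was lost without control 1 (adjusted p = 0.0676) or severe asthma 3 (0.0511). That of Chil3 was lost without control 1 (adjusted p = 0.0825), without severe asthma 3 (0.059) and with the replicate block (0.0517), and that of Itgax without both libraries numbered 1 (0.0697). Chil3 and Lyz2 have close paralogs whose reads the counting could split, so their values are uncertain.

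**Figure D2:**
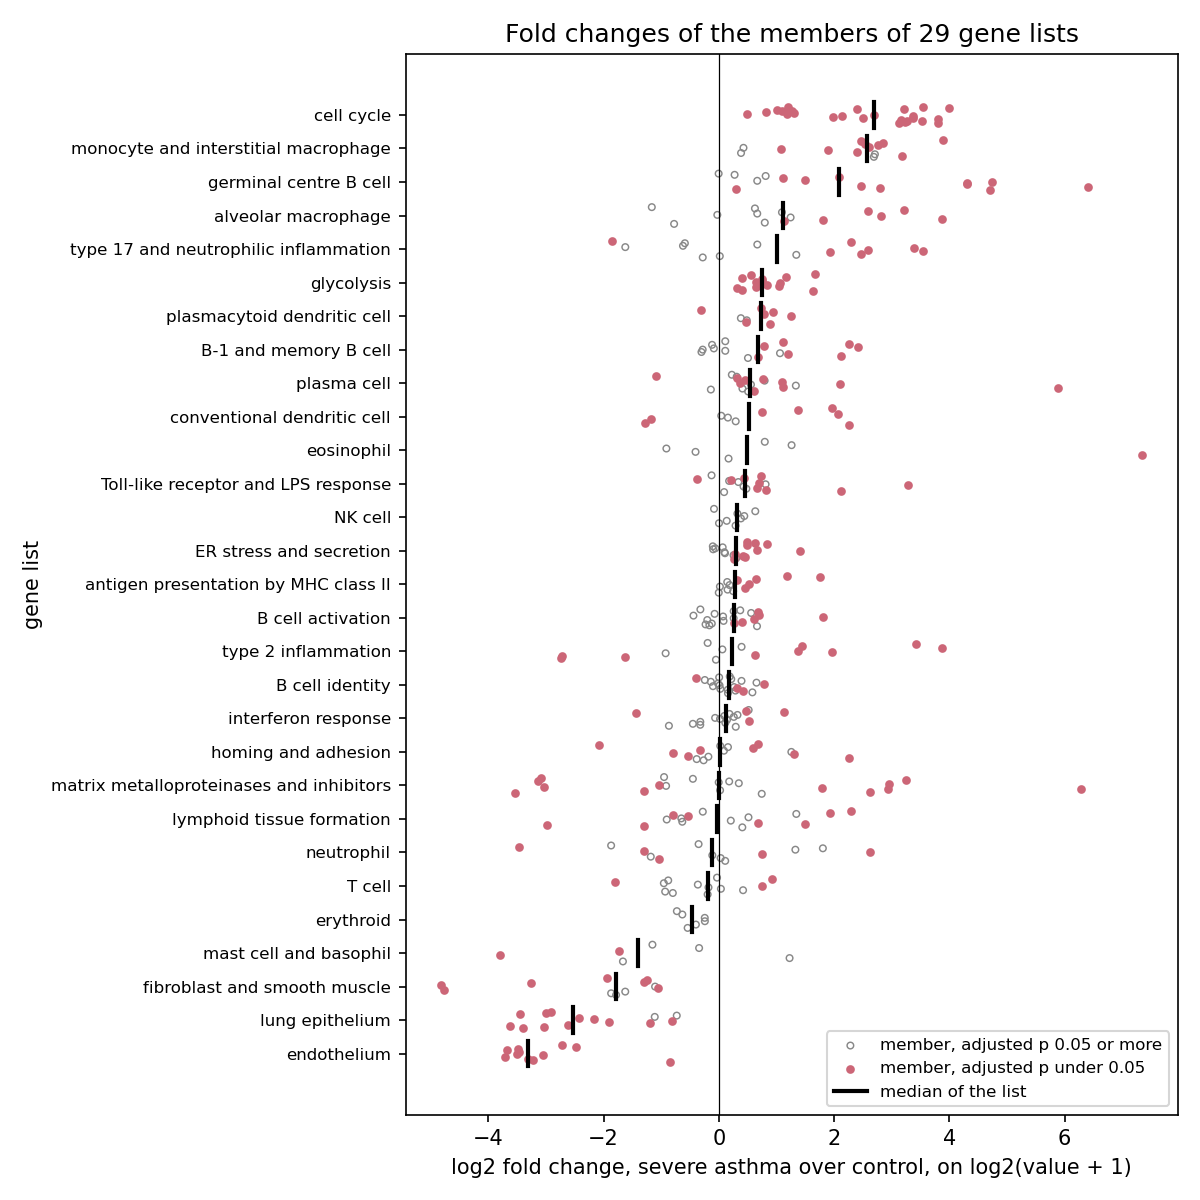
Log2 fold change (severe asthma over control, on log2(value + 1)) of each tested member of 29 gene lists, sorted by the list median, which is drawn as a black bar. Filled points passed an adjusted p of 0.05; the medians run from -3.31 for endothelium to 2.70 for cell cycle.

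Inflammatory genes went different ways. In the list of Toll-like receptors and the LPS response, 8 of 16 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.00677, adjusted p = 0.445 with an estimated correlation). Tlr4, the LPS receptor, rose from 210.1 ± 16.8 to 371 ± 23.5 (SD, n = 3, log2 fold change 0.82), Ticam1, its adaptor TRIF, by 0.73 and Cd14, which macrophages also carry, by 3.29 on the log2 scale, the last losing its call without both libraries numbered 1 (adjusted p = 0.0672). Of 14 genes of type 17 and neutrophilic inflammation, 6 rose and 1 fell in either adjustment (median 1.01, camera adjusted p = 0.233). That median was 1.66 without control 1 and 0.667 without control 2. Cxcl3, a neutrophil chemoattractant, rose from 19.7 ± 10.6 to 200.0 ± 20.2 (3.40), and Cxcl1 rose by 3.54 on the log2 scale (adjusted p = 0.0114, but 0.0577 with the replicate block). Il1b (2.46) and Cxcl2 (2.58) rose too, and without both libraries numbered 1 their calls and that of Cxcl1 were lost (adjusted p 0.082 to 0.13). Macrophages also make these 4 products, and macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages). Of 14 type 2 genes, 6 rose and 3 fell in either adjustment (median 0.23, camera adjusted p = 0.675), with rises of Arg1, an enzyme of alternatively activated macrophages (8.66 ± 2.19 to 116 ± 72.4, log2 fold change 3.43), and Crlf2, a chain of the TSLP receptor (0.63). The type 2 median was 0.673 without severe asthma 1 and 0.4 without severe asthma 3. Il33, an alarmin of epithelial and endothelial cells, fell from 151 ± 81.6 to 22.6 ± 12.02 (-2.74, adjusted p = 0.0104, but 0.0677 with no filter on low values). Of 18 interferon response genes, 3 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.79), with Bst2 among the risen (0.47). Ifi44 fell (-1.43), a call lost with no filter on low values and without any 1 severe asthma library (adjusted p 0.0521 to 0.0787).

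Markers of further immune cells moved unevenly. Of 9 genes of plasmacytoid dendritic cells, which carry B220 themselves, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.74, camera adjusted p = 0.00893, adjusted p = 0.417 with an estimated correlation), including Pacsin1 (337 ± 31.6 to 647 ± 25.2, SD, n = 3, log2 fold change 0.94), Siglech (0.88) and Irf8, which B cells also express (0.74). The fallen gene was Tcf4 (-0.31), a call lost without severe asthma 2 (adjusted p = 0.0564) or 3 (0.059). Of 10 conventional dendritic cell genes, 5 rose and 2 fell in either adjustment (median 0.52, camera adjusted p = 0.354), and Flt3 rose from 129 ± 13.2 to 620 ± 47.9 (2.26), while Clec9a (-1.17) and Zbtb46 (-1.27) fell. Their calls were lost with limma-voom (adjusted p = 0.0793 and 0.0924), with no filter on low values (0.114 and 0.157) and without severe asthma 2 (0.0951 and 0.143) or 3 (0.0777 and 0.134). That of Clec9a was also lost without severe asthma 1 (adjusted p = 0.055), and that of Zbtb46 without control 3 (0.0527) and with curated transcripts (0.213). Of 13 neutrophil genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.11, camera adjusted p = 0.356). Without severe asthma 1 the neutrophil median was -0.388, and without control 1 it was -0.044. Ltf, encoding lactoferrin, fell from 1552 ± 486 to 138 ± 34.9 (-3.46) and S100a9 from 131 ± 20.1 to 63.0 ± 1.35 (-1.03), while Mmp8, neutrophil collagenase (2.63), and Csf3r, the receptor for G-CSF (0.75), rose. Both of these calls were lost with no filter on low values (adjusted p = 0.0727 and 0.0725) and without severe asthma 2 (0.0586 and 0.087) or 3 (0.0516 and 0.0675), that of Mmp8 also without both libraries numbered 1 (0.0684), and that of Csf3r without severe asthma 1 (0.0563). In control, Ltf was highest in library 2 (2081, against 1128 and 1447), as was the airway epithelium gene Bpifa1 (5392, against 2752 and 3693). S100a9 was not (116, against 123 and 154), so the fall of Ltf cannot be assigned to neutrophils alone. Eosinophil genes had a median of 0.48 (camera adjusted p = 0.739), but of 0.025 without control 2 and 0.807 without control 1. Of the 6 tested, 1 rose (also adjusted over the list alone) and 0 fell. That gene, Prg2, encoding eosinophil major basic protein, had 0, 1 and 1 reads in control and 347, 300 and 144 in severe asthma (adjusted p = 0.000223). Of 13 T cell genes, 2 rose and 1 fell (2 and 0 adjusted over the list alone, median -0.19, camera adjusted p = 0.438), with Lck rising by 0.76 on the log2 scale. The T cell median was -0.024 without control 3 and -0.331 without control 1. Themis had the fall (-1.80), a call lost with limma-voom, with no filter on low values and without any 1 library other than control 1 (adjusted p 0.0537 to 0.132). Of 8 natural killer cell genes, 0 rose and 0 fell with limma in either adjustment (median 0.31, camera adjusted p = 0.469), although 2 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Without severe asthma 2 the natural killer cell median was 0.07. Of 6 mast cell and basophil genes, 0 rose and 2 fell in either adjustment (median -1.41, camera adjusted p = 0.0908, but 0.017 without severe asthma 2). These were Hdc (-1.74) and Gata2 (-3.80), whose calls were lost with no filter on low values (adjusted p = 0.0725 and 0.0534), and that of Gata2 with limma-voom (0.0785). Control 1 held more Gata2 (1631, against 462 and 490) and Zbtb46 (231, against 92.0 and 95.5) than controls 2 and 3. The endothelial gene Cdh5, which also fell, had the same order in control (9740, against 2794 and 3569). The falls of Gata2 and Zbtb46 therefore cannot be assigned to mast cells or dendritic cells alone.

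Genes of structural lung cells were lower in severe asthma. All 11 endothelial genes fell, also adjusted over the list alone, with a median log2 fold change of -3.31 (camera adjusted p = 3.88e-07, adjusted p = 0.433 with an estimated correlation). Egfl7, secreted by endothelium, fell from 1552 ± 902 to 147 ± 105 (SD, n = 3, log2 fold change -3.48, adjusted p = 0.0122, but 0.0506 with no filter on low values). Of 14 lung epithelium genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone, median -2.52, camera adjusted p = 1.72e-07, adjusted p = 0.417 with an estimated correlation). Scgb1a1, the club cell secretoglobin, fell from 7764 ± 937 to 3427 ± 663 (-1.19, adjusted p = 0.00241), Scgb3a2 from 601 ± 106 to 160 ± 36.0 (-1.91) and Krt8 from 332 ± 81.0 to 73.8 ± 22.8 (-2.17). Sftpc, the surfactant gene of alveolar type II cells, fell from 18520 ± 16150 to 1662 ± 1292 (-3.41, adjusted p = 0.0239), with 37170 in control 1 against 9169 and 9213 in controls 2 and 3. Its call was lost without control 1 (adjusted p = 0.0746), severe asthma 2 (0.074) or severe asthma 3 (0.0802). Of 11 fibroblast and smooth muscle genes, 0 rose and 7 fell (0 and 11 adjusted over the list alone, median -1.78, camera adjusted p = 8.1e-06, adjusted p = 0.417 with an estimated correlation). Myh11 (-1.93) and Acta2 (-1.30), contractile genes of smooth muscle, fell, calls lost with no filter on low values (adjusted p = 0.0504 and 0.0547).

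The calls on the fibrillar collagen genes Col1a1, Col1a2 and Col3a1 and on the haemoglobin genes depended on the replicate block. Col1a1, Col1a2 and Col3a1 had log2 fold changes of -1.78, -1.87 and -1.62 with adjusted p of 0.0613, 0.0536 and 0.0721, and of 0.00158, 4.55e-05 and 0.000115 with the replicate block. Without control 2 or severe asthma 1 these 3 genes passed as well (adjusted p 0.0351 to 0.0447), and with DESeq2 (0.00827 to 0.0178). The authors' deposited table lists all 3 as fallen, with q-values of 6.25e-05 to 0.000359. Of 6 erythroid genes, 0 rose and 0 fell with limma in either adjustment, 0 had an unadjusted p under 0.05 and edgeR and DESeq2 called 0, while 4 passed with the replicate block. Their median log2 fold change was -0.47 (camera adjusted p = 0.438, but 0.0272, direction down, with the replicate block). That median turned to 0.085 without control 3 and to 0.161 without severe asthma 2, and was -0.932 without control 2. Hba-a1 had 1645 ± 1053 in control and 1149 ± 738 in severe asthma (SD, n = 3, log2 fold change -0.54, adjusted p = 0.642, with the block 0.00108), Hba-a2 an adjusted p of 0.733 (with the block 0.0168) and Hbb-bs one of 0.825 (with the block 0.049). The haemoglobin genes are near-identical copies, so their values are uncertain. Il5ra, an eosinophil marker that B-1 cells also carry, had a log2 fold change of -0.40 (adjusted p = 0.0551, with the block 0.0475), and passed without control 1 (0.00114).

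Non-coding RNA was compared in a table of its own. Of 4395 genes tested, 193 rose and 281 fell, and the groups did not overlap for 26.5% of the genes, where chance gives 10%. With scaling by total reads alone 140 rose and 346 fell. Neat1, the RNA that scaffolds paraspeckles, fell from 8340 ± 352 to 3017 ± 264 (SD, n = 3, log2 fold change -1.47, SE 0.086, adjusted p = 1.72e-19), with no overlap between the groups. Gm46530 (-1.23) and the small nucleolar RNA Snora31 (-1.21) fell as well. Lockd, transcribed next to the cell cycle inhibitor Cdkn1b, rose from 19.7 ± 6.32 to 60.9 ± 2.00 (1.62, adjusted p = 1.76e-05), and Gm32276 (2.33) and Gm36809 (1.77) rose too. Empirical Bayes pools the spread over the genes of a table, and it pooled more here than for mRNA. Neat1 had an unadjusted limma p of 3.91e-23, while the mRNA gene Ccr6 (1.31, SE 0.064) had one of 3.91e-08. The p-values of both tables therefore cannot be compared. Without severe asthma 2 there were 83 risen and 167 fallen genes, without severe asthma 3 there were 108 and 175, and without severe asthma 1 there were 121 risen. Because no source states that strand was used, reads of a non-coding gene and of an overlapping coding gene cannot be separated.

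The authors' deposited table of called genes holds 843 risen and 2134 fallen genes. Of these, 2675 had a tested mRNA gene here, and 2377 of them passed in the same direction and 0 in the opposite one. The authors' deposited table of cellular components gives extracellular matrix 211 of 2618 called genes against 474 of 23407 annotated genes (q = 1.49e-74). In the authors' deposited table of biological processes cell-substrate adhesion had 132 of 2586 called genes against 337 of 23174 (q = 2.46e-37), and in their deposited table of pathways ECM-receptor interaction had 49 of 1153 against 88 of 8980 (q = 2.59e-19). Genes of structural lung cells were lower in the same libraries, so these terms need not describe B cells.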

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

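The tests on macrophage RNA, on a lower share of B cells, on control 1 and on RNA of structural cells were chosen after the result was seen.

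Non-coding transcripts of coding genes, which the comparisons leave out, drew attention because 1076 of 7185 tested rose in severe asthma, while 808 fell. Such rises were no more frequent than among the mRNA genes, where 3262 of 15759 rose. For 1692 of the 1884 non-coding transcripts past the threshold the coding transcript of the gene passed in the same direction, and for 1 in the opposite one. Reads count for every isoform they overlap, so both transcripts share reads and this match is no separate evidence.

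The 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.1. With limma the real split called 5525 mRNA genes and 474 non-coding genes, and it alone (1 of 10) gave as many, the highest other split calling 0. For the gene lists the real split gave 14 past the threshold and 3 of the 10 splits gave as many, the highest being 16 for control 1, control 3 and severe asthma 3 against the rest. That split parts 1 of the same-numbered pairs, while the other splits that part all 3 pairs gave 14, 13 and 8 lists.

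Mmp12 and macrophage genes were higher together in severe asthma. With the other cells in unchanged proportion, a lower share of B cells would raise the markers of all other cell types. Lung epithelium genes, however, had a median log2 fold change of -2.52 and monocyte and interstitial macrophage genes 2.57, which argues against that case only. A lower share of B cells with a changed mix of other cells should lower the B cell identity genes. Their list did not fall (median 0.17, camera adjusted p = 0.492). As its change was not beyond that of other genes, a small drop in share stays open. Scaling by total reads alone left Mmp12 at 6.15. RNA of macrophages carried through the B220 selection stays open: 10 of 14 macrophage genes rose, 1 of the 14 stands in another list, all 14 had mean values of at least 10 in control, and the most abundant, Lyz2 and Apoe, reached 67970 and 34150 in severe asthma. These values restate the pattern, and each library pools the selected cells, so macrophage RNA and expression of Mmp12 by B cells cannot be told apart.

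Structural lung cell genes were lower in severe asthma. For the endothelial genes control 1 is not the whole cause, because without it their list kept a median log2 fold change of -2.79, and scaling by total reads alone gave -3.46 for the same list. The medians of the epithelium, endothelium and fibroblast lists, types that the B220 selection should remove, were all at or below -1.78, which restates the pattern. Less RNA of these cells in the severe asthma libraries and a change within them in inflamed lung therefore cannot be told apart.

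Germinal centre and cell cycle genes were higher in severe asthma. No single library carried this, as the lowest median log2 fold change of the germinal centre list over the 6 fits without 1 library was 1.59, without control 1, and scaling by total reads alone gave 1.99. A larger share of germinal centre B cells among the lung B cells of severe asthma is a hypothesis for this pattern that was not tested here. Macrophage genes were higher in the same libraries, so the cell cycle genes cannot be assigned to B cells alone.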

How the results depend on the processing

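The edgeR quasi-likelihood test, the mean of at least 10, curated transcripts and leaving out both libraries numbered 1 were chosen after the data had been seen. Depth and 3 libraries per group limit what small changes can be called. Over all alternatives run, none of the 147 named genes turned direction with a call. The cause of a lost call was not tested. No filter lost 48 named calls, limma-voom 21, and leaving out severe asthma 3 or 2 lost 36 and 29. The alternative that leaves out immunoglobulin genes was not run, because 0 of 38661 gene symbols matched those of constant or variable region genes.

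Against the 5525 mRNA genes called, 6242 passed with the replicate block (5373 of the 5525 among them) and 4970 with edgeR. The pairing moved no count over a whole table, nor that of the lists, by over 1.5 times: with the block 3528 mRNA genes rose and 2714 fell, 543 non-coding genes and 15 lists passed, and Mmp12 had an adjusted p of 0.0108. Among the 147 named genes and 29 lists, the block changed no call other than those given with the results. With no filter 1699 mRNA genes passed (1312 risen, 387 fallen, over 21774 tested), with a 2-fold minimum 2469 (792 risen), and with glmTreat 753 (433 risen, 320 fallen). Total reads alone gave 1920 risen and limma-voom 1352 fallen. Leaving out 1 library gave 2303 (without severe asthma 2) to 5644 mRNA genes, 1575 to 3401 risen and 728 to 2335 fallen. Without severe asthma 3 there were 2409, and without both libraries numbered 1 there were 6074.

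Against the 474 non-coding genes called, and over other sets of tested genes, DESeq2 called 217 (87 risen, 130 fallen), limma-voom 263 (119 fallen), RLE factors 303 (113 risen), the stricter filter 253 (115 risen, 138 fallen), glmTreat 87 (39 risen, 48 fallen), edgeR 285 (119 risen, 166 fallen) and a mean of at least 10 289 (128 risen, 161 fallen), and the pseudocount of 0.1 left 184 fallen. Leaving out 1 library gave 250 to 482, with 83 to 194 risen and 167 to 288 fallen, the lowest without severe asthma 2.

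Mmp12 kept its direction in 19 alternatives and its call in 18, with log2 fold changes of 5.89 to 7.07 over the fits without 1 library, and 6.22 (adjusted p = 0.0753) with limma-voom. Of the 14 gene lists past the threshold, 0 passed with an estimated correlation. Leaving out 1 library gave 13 to 15 lists. Fry found 27 lists changed in either direction and 19 in 1 direction. The directional test lost alveolar macrophage (adjusted p = 0.143), gained type 17 (0.0154), type 2 (0.0192), and conventional dendritic cell, eosinophil, and mast cell and basophil (0.00881 each), and turned homing and adhesion to up (0.0443).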

Other observations

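The 8 gene lists and the tests on same-numbered libraries were chosen after the result was seen, as were all genes named from these lists. The lists were tested as a family of their own with camera.

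Further B cell and metabolic lists were tested. Of 14 genes of mismatch repair and somatic hypermutation, 7 rose and 0 fell (median log2 fold change 0.40, adjusted p = 0.00239, adjusted p = 0.399 with an estimated correlation). Polh, an error-prone polymerase, rose from 281 ± 49.2 (SD, n = 3) to 609 ± 47.5 (log2 fold change 1.12, adjusted p = 0.00189), and Ung, which removes uracil, rose by 0.88 on the log2 scale. Of 9 genes of age-associated B cells, 6 of which other lists also hold, 8 rose and 0 fell (median 2.11, adjusted p = 4.89e-05, adjusted p = 0.351 with an estimated correlation), with Fcrl5 at 190.4 ± 34.3 in control and 560.4 ± 25.6 in severe asthma (1.57) and Cxcr3 at 41.9 ± 4.76 and 226 ± 126 (2.27). Itgax, Itgam and Cd68 of this list are macrophage markers too, and macrophage genes were higher in the same libraries (median 2.57 for monocytes and interstitial macrophages). Of 25 genes of oxidative phosphorylation, 23 rose and 0 fell (median 0.49, adjusted p = 1.57e-08, adjusted p = 0.351 with an estimated correlation), with Cox4i1 at 0.64 and Sdhb at 0.52. Of 21 genes of cholesterol synthesis, 13 rose and 0 fell (median 0.48, adjusted p = 3.54e-05, adjusted p = 0.351 with an estimated correlation), including Mvd (0.95), Sqle (0.82) and Dhcr7 (0.75). Oxidative phosphorylation and cholesterol synthesis are not particular to B cells, so the higher macrophage genes (median 2.57) limit the reading of these lists too. Of 11 genes of regulatory B cells, 4 rose and 1 fell (median 0.09, adjusted p = 0.191), with Havcr1, the receptor TIM-1, rising from 41.9 ± 10.3 to 244 ± 14.4 (2.54), while Il10 had 4.84 ± 2.04 and 18.4 ± 15.5 (adjusted p = 0.139).

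Macrophage and matrix genes went opposite ways. Of 16 genes of lipid-associated macrophages, 13 rose and 1 fell (median 1.99, adjusted p = 2.17e-05, adjusted p = 0.351 with an estimated correlation), among them Msr1, a scavenger receptor (18.6 ± 20.3 to 344 ± 96.6, log2 fold change 4.62), Lgals3 (2.92), Ctsd (2.75) and Spp1 (2.50), and Cd36 fell (-1.47). Of 22 genes of basement membrane and collagen, 1 rose and 17 fell (median -2.54, adjusted p = 1.57e-08, adjusted p = 0.351 with an estimated correlation), including Lama3 (304 ± 298 to 18.6 ± 5.54, -3.56) and Fbln5 (-2.53). The gene that rose, Fn1, encodes fibronectin (2734 ± 1853 to 8113 ± 1679, 1.78, adjusted p = 0.0499).

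Immediate early genes as a list did not pass the test between the groups (1 of 23 rose and 0 fell, median log2 fold change 0.07, mean 0.15, camera direction down, adjusted p = 0.741). A median of 83.6% of their within-group variance went with the replicate number, above 99.04% of 10000 random lists of like expression, whose median was 67.5%. The 6 erythroid genes showed 99.6% against 58.0%, above 100% of the random lists. Both lists were set against random ones only after the pattern was seen, and the haemoglobin genes are near-identical copies, so these percentiles decide nothing about its cause. Hba-a1 had 1638, 596 and 2702 in controls 1 to 3 and 1212, 381 and 1853 in severe asthma 1 to 3. The named genes of the lung epithelium, endothelium and fibroblast lists were highest in library 1 of both groups, except Scgb1a1, Scgb3a2 and Acta2. Sftpc had 3150 in severe asthma 1 against 837 and 997, and 37170 in control 1 against 9169 and 9213. Cdh5 had 1078 in severe asthma 1 against 314 and 343, and 9740 in control 1 against 2794 and 3569. Whether same-numbered libraries share a condition stays open, and the labels name none.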
